A study of Mus musculus with 60 samples.

How the data were processed

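Whole-tissue RNA was measured in 15 tissues of female C57BL6/J mice, with 4 replicates per tissue and 60 libraries. According to the labels, the mice were perfused through the heart with buffered saline and EDTA, and tissues were kept in RNAlater. RNA was extracted with TRIzol, treated with DNase, fragmented by heat and primed with barcoded oligo(dT), so that reads come from the 3' ends of transcripts. Libraries were sequenced on a NextSeq500. No molecular identifiers are described. Intervals and limits on folds pool the counts of the 4 libraries of a tissue, so they cover counting error only.

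The deposited table holds counts, which are sequenced reads assigned to each gene per the submitters' processing notes. These name FastQC for read quality, STAR for alignment to the mouse genome build mm10 and featureCounts for assignment to genes, and their versions are not given in the sources used here. Of the 54532 genes in the table, 54495 matched GENCODE mouse release 21 by Ensembl ID, which gave gene type and position. All values in the table were whole numbers, and no column was left out. The depth of a library is its total count. The strand setting of the assignment is not given in the sources used here, so a gene that overlaps another on the opposite strand may share its reads.

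Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr by tissue with a minimum count of 10 and a minimum total of 15, and libraries were scaled by TMM. Each tissue was compared with the equally weighted mean of the other 14 in a fit of all 60 libraries with tissue as the only term. The same fit compared the mean of 6 immune tissues with that of the other 9, where the error is that between replicates within tissues and not that between tissues. Pairs of related tissues were fitted on their own 8 libraries. Each contrast used glmQLFit and glmQLFTest, a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p below 0.05 and an absolute log2 fold change above 1. The SE of a log2 fold change was its size divided by the square root of its F statistic.

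A gene was restricted to a tissue if it was called higher there, had a mean of at least 5 CPM and at least 4 times that of the next tissue, and had its lowest library above all libraries of other tissues. Similarity was the Spearman correlation of log2 CPM with an offset of 1 over the tested genes. Genes with at least 1 read were counted after random thinning of every library to the depth of the shallowest. Lists of marker genes of cell types and immune families, written from general knowledge, were tested with camera on log2 CPM with a prior count of 2, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment ran over all lists of a family of contrasts. A list needed at least 4 measured members, that is, members among the tested genes.

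The genes named were set by a rule. For a tissue these were the 3 genes with the largest log2 fold change among those called higher with at least 50 CPM and every library above all other libraries. For a pair these were the 8 in each direction with at least 20 CPM in the higher tissue and all 4 libraries of 1 tissue above the 4 of the other. For immune tissues these were the 10 in each direction with the widest gap between the tissue means of the classes. From a list up to 4 members with at least 5 CPM on either side were named by the size of their change. Any member that went against the list was named too. Symbols of unnamed gene models were passed over, and some genes that fall under the rule are not reported here. Other genes are stated to have been chosen after their values were seen.

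For a tissue without reads of a gene, the fold is a bound that takes 3 counts over the 4 libraries of that tissue. With 1 to 3 counts the ratio is given with its 95% counting interval. The procedure was tested on simulated data, drawn from a negative binomial distribution around the mean share of each gene at the real depths, with 200 genes changed in 1 tissue. The share of changed genes recovered at a 3-fold and a 6-fold change was 96% and 98% for the lymph nodes, 94% and 93% for the intestine, 93% and 99% for thymus and bone marrow, 96% and 97% for blood and spleen, and 97% and 100% for blood against the other tissues. The unchanged genes gave 2, 4, 1, 1 and 1 calls. In the simulation every gene and tissue had the same dispersion, and the tissues differed in the changed genes only. These were drawn from genes with higher expected counts. The real data do not keep to these settings, so the shares and calls are no error rates of the real comparisons.

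The groups, contrasts, thresholds, lists, rule for naming and most alternatives were chosen before the data were examined. These alternatives were DESeq2 size factors or library totals in place of TMM, no filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, each replicate left out, pairs fitted on all 60 libraries, a 2-fold limit for restricted genes, an estimated correlation, libraries that were not thinned and Pearson correlation. Others were chosen after seeing the data: nuclear protein-coding genes only, without 6 libraries in doubt, and without colon and lung. Each comparison was also repeated with the libraries regrouped in other ways. The labels give no batch, cage or date, and the titles number the 4 libraries of each tissue consecutively. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.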

Results

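RNA of 15 tissues was measured in female C57BL6/J mice of 6 weeks, to follow immune processes across the whole body. Each tissue had 4 replicates, 60 libraries in all, and the labels name 4 mice. Blood was collected as peripheral blood mononuclear cells according to its title, while its tissue label reads whole blood, and it is called blood here. The other tissues were bone marrow, spleen, thymus, inguinal and mesenteric lymph node, brain, colon, small intestine, heart, kidney, liver, lung, skin and the female reproductive tract. The assay read 3' ends of polyadenylated RNA from barcoded oligo(dT) primers, so a count is a sequenced read assigned to a gene. Library totals ran from 353605 counts (female reproductive tract replicate 3) to 5211133 (inguinal lymph node replicate 1), with a median of 2649668. Colon (863924 ± 93949 counts, SD, n = 4) and lung (1027898 ± 132055 counts) were the shallowest tissues on average, and heart (4619154 ± 250674 counts) was the deepest. Of the 54532 genes in the count table, 17394 had no read in any library, and 18562 had enough counts to be tested across all libraries. Thinned at random to the depth of the shallowest library, heart libraries held 11360 ± 38.4 genes with a read and those of the female reproductive tract 15668 ± 585, the lowest and highest of the tissues. Only total counts were matched. Mitochondrial rRNA made up 39.6% ± 1.12 and mitochondrial protein-coding RNA 15.5% ± 1.04 of the heart counts, and nuclear protein-coding genes 43.4% ± 0.825, against 78.3% ± 3.52 in the reproductive tract. Below, levels are in CPM, counts scaled by the normalised library total, given as mean ± SD over the 4 libraries of a tissue, and log2 fold changes are given ± SE.

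Tissue identity set the order of the libraries. The library nearest to each of the 60 libraries came from the same tissue in 60 cases, by Spearman correlation across genes of log2(CPM + 1). The median correlation was 0.974 between libraries of the same tissue (range 0.866 to 0.986) and 0.709 between tissues (0.473 to 0.971). Inguinal and mesenteric lymph node were the closest pair of tissues (median correlation 0.958), followed by spleen and inguinal lymph node (0.941). Brain stood farthest from the rest, and its nearest tissue was heart at 0.639. The female reproductive tract was the least uniform tissue, with a median of 0.897 within it. Genes are not independent replicates, so these correlations describe the libraries only.

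**Figure D1:**
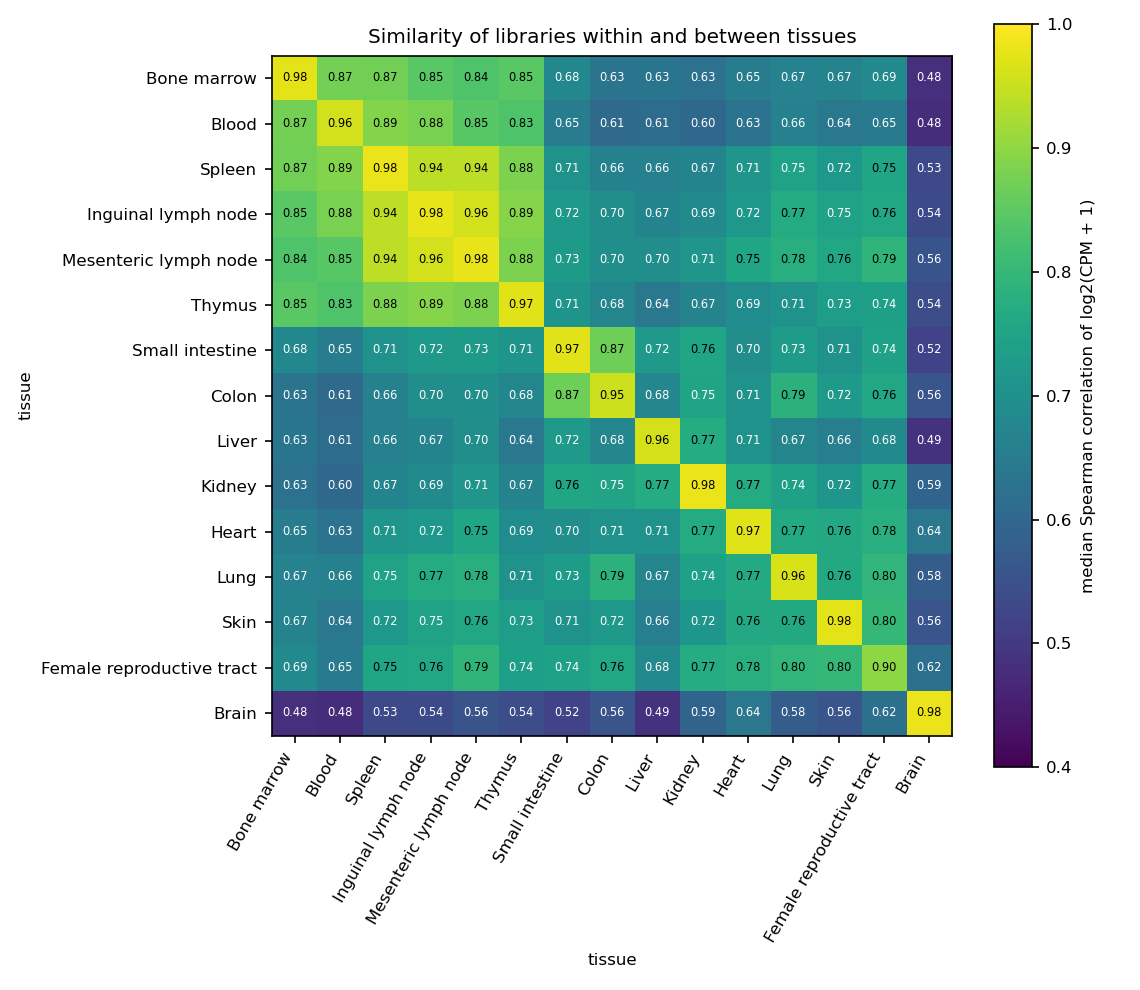
Median Spearman correlation of log2(CPM + 1) across genes between the libraries of each pair of tissues, with tissues on both axes and colour giving the correlation. The cells on the diagonal hold pairs of libraries of the same tissue, where the female reproductive tract is lowest at 0.897, and the inguinal and mesenteric lymph nodes reach 0.958.

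The first comparison asked what sets each tissue apart from the mean of the other 14, beginning with brain, heart, kidney and liver. Brain was led by Mobp, a myelin protein (ENSMUSG00000032517, chromosome 9, 120149707 to 120181484 in mm10), at 921 ± 25.99 CPM against 2.37 in the next tissue, by Snap25, a protein of synaptic vesicle fusion, at 1721 ± 51.4 CPM, and by Sncb, beta-synuclein, at 333 ± 7.51 CPM. Heart was led by the ventricular myosin light chains Myl2 (19463 ± 891 CPM) and Myl3 (13026 ± 340 CPM) and by the myosin heavy chain Myh6, at 11927 ± 145 CPM against 46.1 in lung. In kidney the leading genes were Kap (12556 ± 2681 CPM), the phosphate transporter Slc34a1 of the proximal tubule (3367 ± 83.9 CPM) and Miox, an oxygenase of myo-inositol (2313 ± 104 CPM). Liver was led by Gc, the vitamin D-binding protein (10322 ± 85.1 CPM), the carboxylesterase Ces1c (4807 ± 217 CPM) and the serine protease inhibitor Serpina3k (10397 ± 2647 CPM). All 12 measured members of the neuron and glia list were called higher in brain (camera adjusted p = 2.36e-10), all 10 cardiomyocyte genes in heart (1.89e-13), all 11 kidney epithelium genes in kidney (8.07e-16) and all 12 hepatocyte genes in liver (4.51e-15). Among the hepatocyte genes were albumin, Alb (log2 fold change 13.63 ± 0.19), and Ahsg, fetuin-A (13.80 ± 0.14). Each of these counts was the same when adjusted over the list alone.

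These organs also differed in immune and other gene groups. In liver, 13 of 17 complement genes were higher (camera adjusted p = 1.32e-10), among them Cfi, which cleaves activated complement proteins (log2 fold change 10.43 ± 0.18), and C9 of the membrane attack complex (10.83 ± 0.17). Cfd, the factor D made by adipocytes, went against the list at -2.12 ± 0.80. All 5 Kupffer cell genes were higher in liver (camera adjusted p = 0.00147; adjusted p = 0.0806 with an estimated correlation), led by the lectin Clec4f at 10.83 ± 0.20. Brain was lower in 8 of 9 genes of MHC class II (camera adjusted p = 1.34e-07), such as H2-Aa (-6.68 ± 0.23) and the invariant chain Cd74 (-6.34 ± 0.21). All 9 MHC class I genes were lower in brain too (1.46e-07; adjusted p = 0.0732 with an estimated correlation), with H2-K1 at -5.08 ± 0.20, and so were 15 of 19 pattern recognition receptors (0.000241), with Tlr1 at -3.86 ± 0.47. In heart, 8 of 9 endothelial genes were higher (9.53e-06), with the receptors Kdr of vascular endothelial growth factor (2.92 ± 0.10) and Flt1 (2.85 ± 0.11). All 6 measured genes encoded in the mitochondrial genome were higher too (9.53e-06; adjusted p = 0.153 with an estimated correlation), with mt-Nd5 at 4.6 ± 0.12. In kidney, 11 of 13 cell cycle genes were lower (1.51e-05; adjusted p = 0.0835 with an estimated correlation), led by Aurkb at -4.05 ± 0.64, while Tyms went against the list at 0.53 ± 0.13. Adjusted over the list alone, each of these counts was the same.

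Lung, skin and the female reproductive tract formed the next group. Lung was led by the secretoglobin Scgb1a1 of club cells (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), at 94031 ± 596 CPM, and by the surfactant proteins Sftpc (25446 ± 995 CPM) and Sftpa1 (4679 ± 281 CPM). Skin was led by the keratin Krt77 (11119 ± 437 CPM), the cornified envelope gene Lce1m (3149 ± 204 CPM) and Krtdap (6284 ± 313 CPM), a keratinocyte differentiation protein. The female reproductive tract was led by Akr1cl (259 ± 62.9 CPM), the peptidylarginine deiminase Padi1 (143 ± 106 CPM) and the small proline-rich gene Sprr2f (766 ± 1478 CPM), which stood at 2982 CPM in replicate 4 and between 8.38 and 51.9 in replicates 1 to 3. All 11 lung epithelium genes were higher in lung (camera adjusted p = 2.06e-20) and all 9 endothelial genes (1.10e-10), with the adhesion molecule Cdh5 at a log2 fold change of 4.65 ± 0.09 and the angiopoietin receptor Tek at 4.40 ± 0.14. In skin all 10 keratinocyte genes (8.07e-16), all 10 skeletal muscle genes (5.91e-12) and all 5 mast cell genes (0.000861) were higher, the last led by the chymase Mcpt4 (5.63 ± 0.29) and including the carboxypeptidase Cpa3 (4.09 ± 0.20). The female reproductive tract was higher in all 10 uterus and oviduct genes (6.42e-15), all 4 ovary genes (1.61e-06) and all 8 smooth muscle genes (7.06e-09). Examples were Hoxa10 (7.47 ± 0.19), a patterning gene of the uterus, Inha (7.08 ± 0.19), a subunit of inhibin, and Zp3 (6.52 ± 0.40), a protein of the oocyte coat. None of these counts moved when adjusted over the list alone.

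The intestine was the last of the solid organs. Small intestine was led by the alpha-defensins of Paneth cells Defa24 (32587 ± 7587 CPM), Defa30 (10969 ± 2595 CPM) and Defa22 (3915 ± 1525 CPM). Defensin genes are near-identical copies, so reads may be split between them, and Defa24 also stood at 394 CPM in brain replicate 3 and 242 CPM in liver replicate 4, against 27.3 CPM or less in the other libraries of those tissues. Colon was led by the goblet cell mucin Muc2 (11983 ± 1880 CPM), the pentraxin Mptx1 (1651 ± 1195 CPM) and Sval1 (470 ± 180 CPM). Colon replicate 2 stood apart in all 3 of them, at 9169, 3440 and 740 CPM. All 11 enterocyte genes (camera adjusted p = 4.12e-14), all 8 Paneth cell genes (2.84e-10) and 10 of 11 enteroendocrine genes (8.23e-09) were higher in small intestine, for example the fatty acid binding protein Fabp2 (log2 fold change 12.15 ± 0.20) and the incretin Gip (10.16 ± 0.19). The enteroendocrine gene Insl5, a relaxin-like peptide, gave -1.06 ± 2.63 there and did not pass the test. Colon was higher in all 11 colonocyte genes (9.16e-14), all 8 goblet cell genes (3.79e-10), all 8 smooth muscle genes (7.68e-09) and all 7 posterior Hox genes (8.69e-08), with Actg2, a smooth muscle actin, at 8.07 ± 0.17. It was lower in 10 of 12 T cell genes (3.62e-05), for example Cd3e at -3.77 ± 0.59. The colon and lung libraries also held less RNA of some classes than the other 52: mitochondrial rRNA made up 0.233% to 0.928% of counts in these 8 libraries and 4.33% to 40.6% in the others, and the nuclear RNA Malat1 0.0151% to 0.0282% against 0.131% to 1.65%. Each count was the same adjusted over the list alone.

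Among the blood-forming organs, blood was led by platelet genes. Ppbp, platelet basic protein, stood at 1568 ± 434 CPM in blood against 415 in bone marrow, with Gp9, a subunit of the receptor for von Willebrand factor, at 407 ± 89.4 CPM and Treml1 at 245 ± 56.4 CPM. Bone marrow was led by Ear6, a ribonuclease of eosinophils (419 ± 30.2 CPM, against 1.51 in spleen), Ngp of neutrophil granules (5979 ± 351 CPM, against 23.05 in blood) and Slc4a1, the anion exchanger of red cells (1877 ± 19.7 CPM). Thymus was led by the recombinase Rag1 (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501) at 1751 ± 334 CPM against 69.0 in bone marrow, with Tbata (472 ± 131 CPM) and Psmb11, the proteasome subunit of cortical thymic epithelium (113 ± 9.51 CPM). In blood all 7 platelet genes (camera adjusted p = 1.12e-09), all 11 B cell genes (1.50e-11), all 12 T cell genes (1.15e-09) and all 9 mature neutrophil genes (1.24e-06) were higher, such as Cd2 (log2 fold change 5.27 ± 0.11) and the receptor Csf3r (5.91 ± 0.14). All 8 fibroblast and matrix genes were lower in blood (1.26e-07), with decorin, Dcn, at -8.11 ± 0.36. In bone marrow all 9 neutrophil precursor genes (1.32e-14), all 10 erythroid genes (7.24e-14), all 6 eosinophil genes (1.69e-07), all 7 B cell progenitor genes (3.87e-08) and all 13 cell cycle genes (1.78e-12) were higher, including cathelicidin, Camp (11.36 ± 0.13), the globin Hbb-bt (9.38 ± 0.20) and Mki67 (6.11 ± 0.11). Globin genes are close copies, so their reads may be shared. In thymus all 11 thymocyte genes (2.89e-16), 7 of 8 thymic epithelium genes (1.13e-07), all 12 T cell genes (1.32e-14) and all 13 cell cycle genes (8.46e-11) were higher, with the T cell receptor constant gene Trbc2 at 6.82 ± 0.08. There 8 of 9 endothelial genes were lower (0.000149), with Kdr at -2.57 ± 0.19, and Pecam1 gave 0.14 ± 0.11 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.292). Adjusted over the list alone, all of these counts were the same.

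The secondary lymphoid organs completed the comparison. Inguinal lymph node was led by Glycam1, a mucin of high endothelial venules (ENSMUSG00000022491, chromosome 15, 103562759 to 103565081), at 4366 ± 1440 CPM against 1286 in mesenteric lymph node, followed by H2-M2, a nonclassical MHC class I gene (94.3 ± 19.1 CPM), and the chemokine Ccl22 (132 ± 9.27 CPM). Mesenteric lymph node was led by the scavenger receptor Marco (495 ± 102 CPM, against 159 in spleen), the mucosal addressin Madcam1 (55.9 ± 3.24 CPM) and the guanylate-binding protein Gbp2b (50.6 ± 18.7 CPM). Spleen was led by Coch, cochlin (589 ± 30.7 CPM), the integrin subunit Itgad (54.1 ± 5.42 CPM) and Spic, a transcription factor of red pulp macrophages (94.7 ± 12.8 CPM). All 9 lymph node stroma genes were higher in inguinal (camera adjusted p = 3.68e-10) and in mesenteric lymph node (2.84e-10), all 12 T cell genes in both (1.01e-14 and 1.32e-14), and 8 and 7 of 8 dendritic cell genes (1.20e-05 and 1.25e-05; Cd209a gave -0.26 ± 0.37 in the mesenteric node), with the homing receptor Ccr7 at a log2 fold change of 5.42 ± 0.12 in the inguinal node. In spleen all 7 stroma and red pulp genes (3.68e-10), all 11 B cell genes (6.09e-14) and all 9 NK cell genes (2.46e-06) were higher, with the complement receptor Cr2 at 5.98 ± 0.10 and the B cell antigen Ms4a1 at 6.32 ± 0.14. Spleen was also higher in 9 of 10 erythroid genes (1.34e-05; adjusted p = 0.0524 with an estimated correlation) and in 11 of 11 monocyte and macrophage genes (6.28e-05; adjusted p = 0.130 with an estimated correlation). Every one of these counts was the same adjusted over the list alone.

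The number of genes called against the mean of the other tissues followed from these profiles and from the scaling. Brain had 5137 genes higher and 2988 lower, and mesenteric lymph node 3186 higher and 851 lower. The 45 leading genes named for the 15 tissues had adjusted p of 4.58e-13 (Sprr2f) or less (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Counts of lower genes are minimum counts, because a gene with no read in a tissue and in another tissue has no finite contrast. Such genes numbered from 747 in brain to 2290 in lung, and none was called. For the same reason the log2 fold change of a gene with no read in some other tissue depends on a small count added by the fit and is no bound, so levels are given for the leading genes. Scaling by library totals alone in place of TMM changed the split between higher and lower calls in many tissues. Heart moved from 3839 higher and 2393 lower to 1499 and 8430, and liver from 3424 and 3100 to 1811 and 7497. The split moved from 3279 and 2666 to 4442 and 1830 in colon, from 4284 and 986 to 6051 and 411 in the female reproductive tract, from 3173 and 1244 to 4835 and 716 in inguinal lymph node, and from 3186 and 851 to 4625 and 510 in mesenteric lymph node. In kidney it moved from 4043 and 1767 to 2902 and 2920, in lung from 3124 and 2278 to 4074 and 1462, and in small intestine from 3694 and 1577 to 3187 and 2127. Spleen went from 3302 and 1701 to 4865 and 981, and thymus from 3513 and 2248 to 5525 and 1353, or to 2284 and 2317 with nuclear protein-coding genes only. Blood had 3366 genes higher and 3297 lower, bone marrow 3270 and 2997, and skin 3423 and 1184. The median over all genes lay off 0 in liver (-0.25), lung (-0.23), bone marrow (-0.21), blood (-0.18), colon (-0.15) and heart (-0.12), and totals alone moved it by -1.26 in heart and -0.98 in liver.

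**Figure D2:**
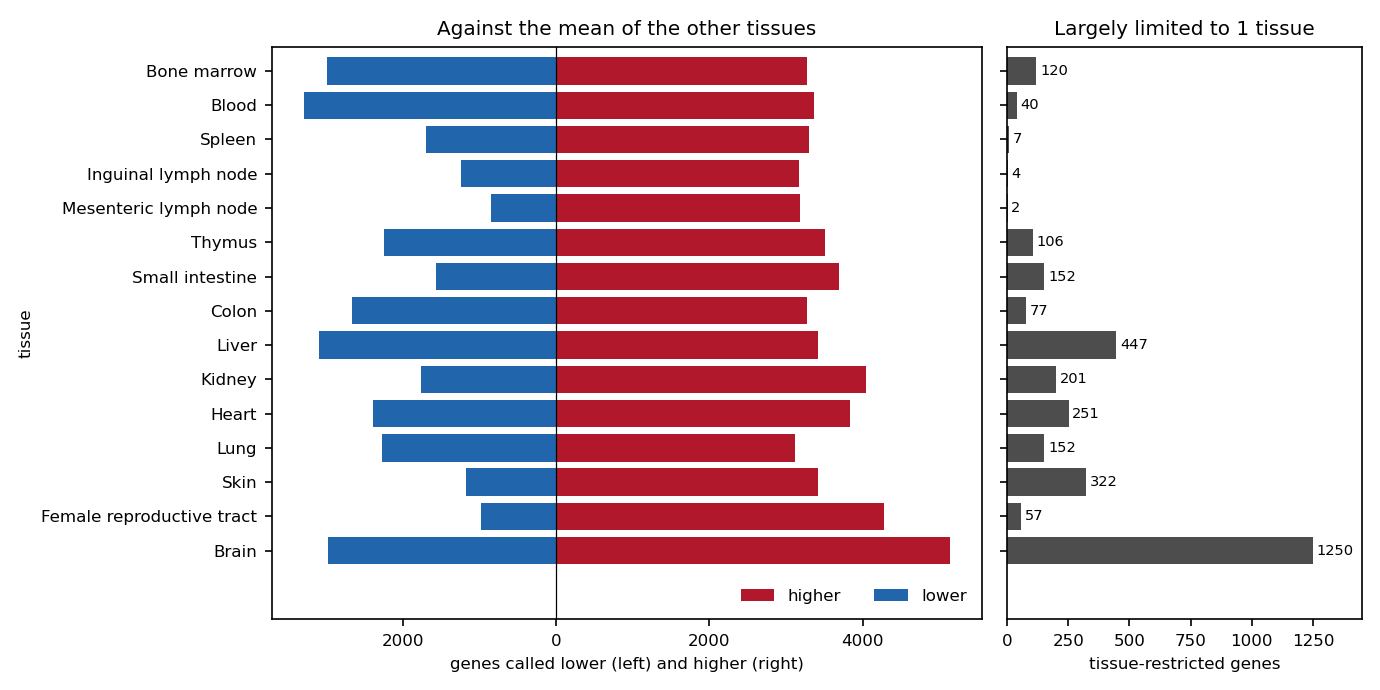
Number of genes called higher (red) or lower (blue) in each tissue against the mean of the other 14, and number of genes restricted to each tissue (grey), with tissues on the vertical axis and 4 libraries per tissue. With TMM scaling, brain has the most genes called higher (5137) and the most restricted genes (1250), and mesenteric lymph node has 2 restricted genes.

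Genes restricted to a tissue, called higher there with a mean of at least 5 CPM, at least 4 times that of any other tissue, and every library above those of all other tissues, made up 3188 of the 18562 tested genes (17.2%). Brain held 1250 of them, liver 447, skin 322, heart 251 and kidney 201, followed by lung and small intestine (152 each), bone marrow (120), thymus (106), colon (77), the female reproductive tract (57, or 88 without its replicates 3 and 4 and 4 libraries of other tissues in doubt) and blood (40). The secondary lymphoid organs held few. Spleen had 7, inguinal lymph node 4 and mesenteric lymph node 2, and the names of the latter 6 were chosen after their values were seen. Those of inguinal lymph node were the cytokine Tnf (22.8 ± 6.18 CPM), the chemokine Ccl12 (18.5 ± 6.80 CPM) and the bactericidal protein family members Bpifb3 and Bpifb2. Those of mesenteric lymph node included Psg22 (7.06 ± 1.85 CPM). Without replicate 2 of every tissue, mesenteric lymph node had 6 restricted genes, and heart had 90 when CPM were scaled by library totals alone.

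The second comparison set the 6 immune tissues (blood, bone marrow, spleen, thymus and both lymph nodes) against the other 9. The genes named were those with the widest gap between the tissue means of the 2 classes. Ptprc, the leukocyte common antigen (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708 in mm10), ran from 563 to 1169 CPM over the immune tissue means and from 4.25 to 52.3 CPM over the others, a log2 fold change of 5.30 ± 0.07. Arhgap15, a regulator of small GTPases (ENSMUSG00000049744, chromosome 2, 43748824 to 44395953), ran from 150 to 226 CPM against 2.03 to 9.61 (5.12 ± 0.06). The costimulatory receptor Slamf1 (6.72 ± 0.14), the GTPase Rhoh (6.26 ± 0.10), the transcription factor Ikzf1 (5.58 ± 0.09) and Was, which controls actin assembly (4.96 ± 0.09), were higher as well, as were Stap1, Arhgap30, Treml2 and Mir142hg, the host gene of a blood cell microRNA (6.15 ± 0.09). Lower in immune tissues were Myh14, a nonmuscle myosin (-6.62 ± 0.17), the motor Myo5b of membrane traffic (-5.52 ± 0.14), Lmo7 (-4.55 ± 0.11), the receptor Bmpr1a (-3.14 ± 0.10) and Cystm1 (-5.02 ± 0.09), with Arhgef19, Car8, Rnd2, Fam135a and Eva1a. The lowest immune tissue mean of Myo5b and of Eva1a was 0 CPM, so their fitted changes depend on a small count added by the fit. These 20 genes had adjusted p of 4.54e-23 (Eva1a) or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 3593 genes were higher and 3540 lower, and of these 942 and 275 had tissue means that did not overlap between the classes. Another 2707 tested genes had no read in a tissue of each class and so no finite contrast. None of them was called, although 1772 were fitted lower by more than the limit of a call. The count of lower genes is therefore a minimum count. Scaling by library totals alone gave 5285 higher and 2592 lower, and the median over all genes lay at -0.16.

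Several lists of lymphoid and antigen presentation genes were higher in that comparison. The plasma cell list was not called, with 6 of 10 genes higher and 1 lower (camera adjusted p = 0.0714, and 0.233 with an estimated correlation). All 12 T cell genes (camera adjusted p = 8.80e-09), all 11 B cell genes (3.05e-08), all 9 MHC class II genes (5.80e-07) and all 9 mature neutrophil genes (0.000188) were higher in the immune tissues. Examples were Cd2 (log2 fold change 6.20 ± 0.11), Ms4a1 (7.03 ± 0.15), the class II chaperone component H2-Ob (5.36 ± 0.10) and Ciita, the class II transactivator (4.33 ± 0.08). H2 genes are related in sequence, so some of their reads may be shared. NK cell genes (8 of 9; 0.000156), dendritic cell genes (7 of 8; 0.000650) and cell cycle genes (12 of 13; 1.41e-05) were higher too, with Nkg7 at 4.37 ± 0.12, Ccr7 at 6.84 ± 0.12 and Mki67 at 3.43 ± 0.11. Of 20 chemokine receptors 15 were higher (5.18e-05), with Ccr6 at 6.59 ± 0.28 and Cxcr5 at 5.70 ± 0.26. The receptor Ackr3 was lower at -2.76 ± 0.19, and Ackr4 (-0.74 ± 0.18) and Ackr2 (-0.83 ± 0.32) had negative values below the size needed for a call, while Ackr1 gave 0.78 ± 0.30. Among 17 cytokines 10 were higher (0.00594), led by Ltb (5.98 ± 0.16) and Lta (5.36 ± 0.34), and 2 were lower, the alarmin Il33 (-2.10 ± 0.22) and Il34 (-1.43 ± 0.15). Il33 had no read in blood, so its value depends on a small count added by the fit. It was not low in all immune tissues: mesenteric lymph node (79.2 CPM) came second only to lung (88.4 ± 13.9 CPM). Il15 (-0.08 ± 0.13), Il18 (-0.14 ± 0.12) and Tslp (-0.29 ± 0.24) also had negative values and did not pass the test. Of 19 pattern recognition receptors 12 were higher (0.00112), with Tlr1 at 3.63 ± 0.15 and Aim2 at 3.35 ± 0.12, and Tlr3 was lower at -1.27 ± 0.11, while Nlrp6 had no read in either lymph node or in skin and cannot be tested. The calls of 8 of 9 MHC class I genes (2.57e-05; adjusted p = 0.0807 with an estimated correlation), 10 of 11 monocyte and macrophage genes (0.00181; adjusted p = 0.160 with an estimated correlation) and 7 of 16 interferon-stimulated genes (0.00398; adjusted p = 0.341 with an estimated correlation) rested on the preset correlation. So did the lower calls of all 8 fibroblast and matrix genes (0.000654; adjusted p = 0.0973 with an estimated correlation) and all 8 smooth muscle genes (0.00146; adjusted p = 0.0836 with an estimated correlation). Adjusted over the list alone, these counts were the same, and 39 of the 57 lists were called, 16 of them with an estimated correlation.

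**Figure D3:**
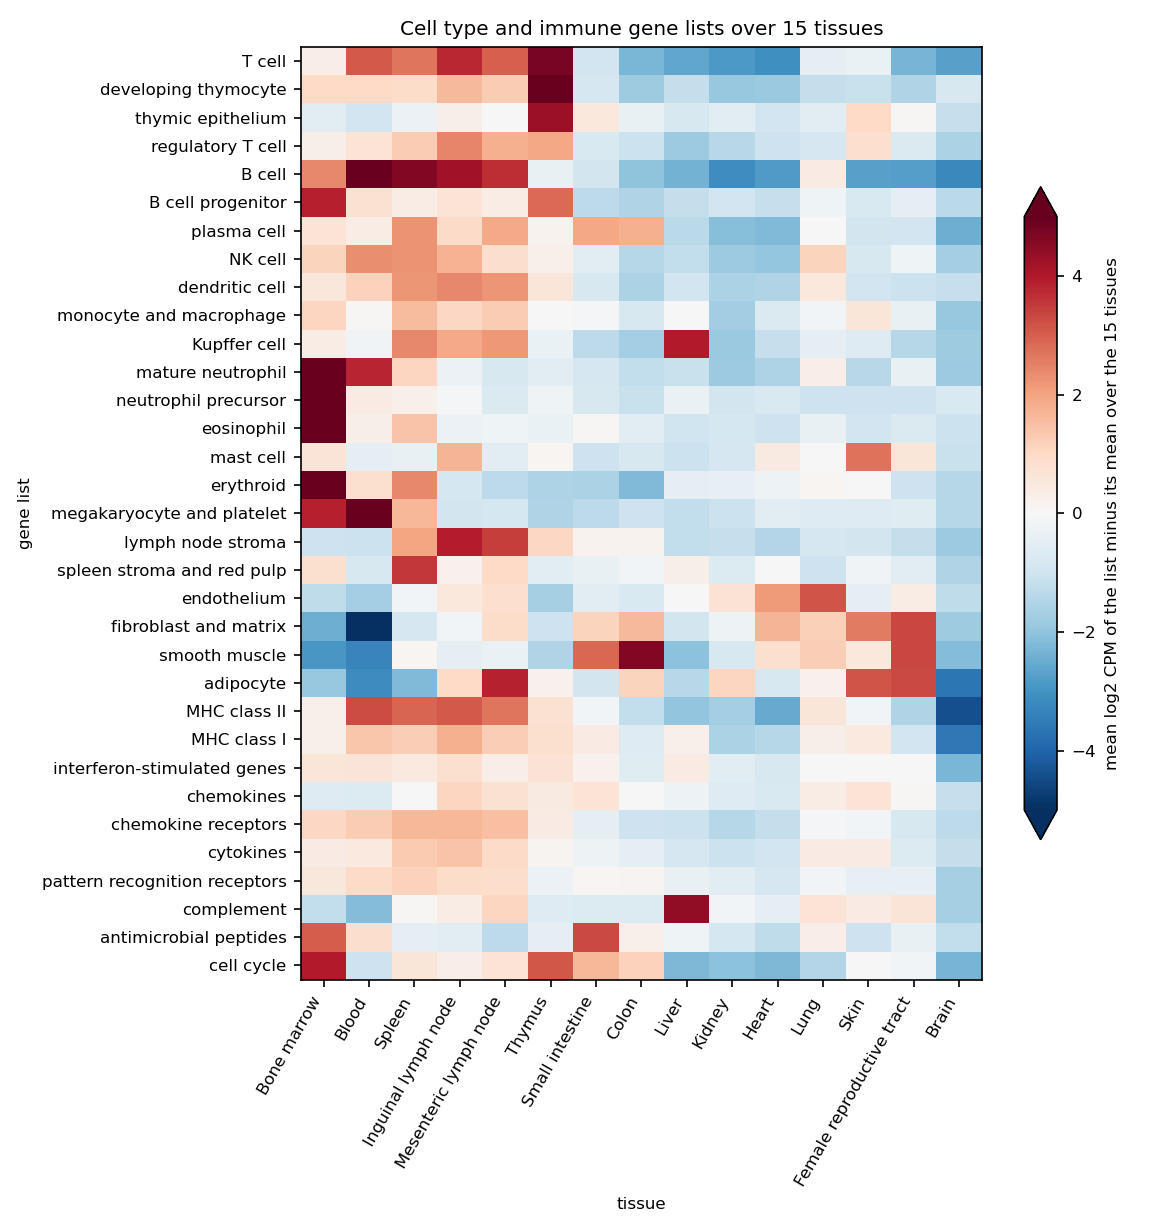
Mean log2 CPM of 33 gene lists (lines of the heat map) in the 15 tissues (columns), each list centred on its mean over the tissues, with colour giving the difference in log2 units. The T cell list is highest in thymus and the B cell list in blood, where all 11 B cell genes were called higher, and the complement list is highest in liver.

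Families of immune genes peaked in different tissues. Of 17 measured complement genes, 12 had their highest mean in liver, among them C3 (7656 ± 513 CPM, with 8417 in replicate 4 and at most 7505 in the others), C9 (326 ± 46.0 CPM, a 501-fold ratio to the second tissue, skin) and the protease Masp2 (200 ± 15.4 CPM). The 3 subunits of C1q, C1qa, C1qb and C1qc, peaked in mesenteric lymph node at 311 ± 59.5, 236 ± 49.6 and 311 ± 60.7 CPM, close to spleen. Of 29 chemokines, 8 peaked in inguinal lymph node and 5 in skin. Of the 29 chemokines, 4 stood at least 4 times above the second tissue, a measure chosen after the values were seen and not tested between families. They were Cxcl15 in lung (1856 ± 110 CPM, 338-fold), Cxcl5 in the female reproductive tract (42.1 ± 37.2 CPM, 19.3-fold, with an SD near its mean), Ccl17 in lung (24.98 ± 5.45 CPM) and Ccl3 in blood (11.8 ± 3.04 CPM). Among 20 chemokine receptors 3 did so, Ccr9, the receptor of Ccl25, in thymus (693 ± 94.5 CPM, 12.4-fold), Ackr4 in skin (102 ± 13.1 CPM, 6.57-fold) and the neutrophil receptor Cxcr2 in bone marrow (156 ± 7.75 CPM, 4.78-fold). Ccl25 itself was highest in small intestine (777 ± 45.6 CPM) and thymus (433 CPM). Among 17 cytokines 2 did so, Il1b in blood (160 ± 32.01 CPM, 4.62-fold, at 112 CPM in replicate 3 and 172 to 182 CPM in the others) and Tnf in inguinal lymph node (4.28-fold), and of 19 pattern recognition receptors 0 did. The measure was met by 8 of 17 complement genes and 11 of 15 antimicrobial peptides. Of the latter, 7 peaked in bone marrow (S100a8 at 13465 ± 671 CPM) and 6 in small intestine (Lyz1 of Paneth cells at 11520 ± 2304 CPM).

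The third comparison set the gut-draining mesenteric against the skin-draining inguinal lymph node, in a fit of their 8 libraries. Pair fits were scaled on their own libraries, so CPM differ slightly from those over all tissues. Igha, the constant region of IgA (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), stood at 883 ± 392 CPM in the mesenteric node against 36.4 ± 32.1 CPM in the inguinal node (log2 fold change 4.59 ± 0.55), Ighg1 at 1300 ± 930 against 14.6 ± 11.1 CPM (6.42 ± 0.92) and Ighg3 at 282 ± 118 against 24.1 ± 14.9 CPM (3.55 ± 0.38). In the inguinal node replicate 2 held 46.4 CPM of Ighg3 and the others at most 18.4 CPM. Constant region genes are similar in sequence, and Igha was 1464 CPM in mesenteric replicate 2 and 628 to 769 CPM in the others. Aldh1a2, which makes retinoic acid, was at 32.5 ± 4.57 against 2.33 ± 1.25 CPM (3.71 ± 0.29), and the mesothelial gene Upk3b at 32.3 ± 15.6 CPM against 1 count in all inguinal libraries, a 516-fold ratio (95% counting interval 92 to 20440). Gpc3 (3.85 ± 0.51), Ptger3 (3.50 ± 0.72) and Agt (4.84 ± 0.88) were higher too, the last with 97.3 CPM in mesenteric replicate 4 and 6.83 to 18.3 CPM in replicates 1 to 3. The inguinal node was higher in Ccl8, a chemokine of skin macrophages (112 ± 64.6 against 2.21 ± 0.868 CPM, -5.69 ± 0.49), Ccl12 (-2.92 ± 0.42), H2-M2 (-2.66 ± 0.15), Tnf (-2.18 ± 0.25), S100a4 (-2.16 ± 0.24), Ly6i (-2.14 ± 0.32), Ptn (-2.87 ± 0.62) and S100a9 (-2.20 ± 0.59). In each of these 16 genes the 4 libraries of 1 node lay above the 4 of the other, as the rule for naming requires, and adjusted p was 0.0160 (S100a9) or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

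Of 13164 tested genes, 716 were higher and 234 lower in the mesenteric node. Mitochondrial rRNA made up 14.3% ± 2.09 of counts in the mesenteric and 5.92% ± 1.58 in the inguinal node. Its ratio to mitochondrial protein-coding RNA was 5.70 ± 0.190 against 2.81 ± 0.424, and the libraries of the nodes overlapped in neither measure. Of 10 immediate early and heat shock genes 4 were higher, Hspa1a (2.82 ± 0.58), Hspa1b (2.00 ± 0.42), Dusp1 (1.74 ± 0.22) and Fos (1.62 ± 0.25), while Ier2 (-0.83 ± 0.10) and Junb (-0.82 ± 0.11) were lower by less than the limit of a call. That list was not called (camera adjusted p = 0.3345; 0.671 with an estimated correlation), and it and the shares were looked up after the fits. The mast cell list was lower in 4 of 4 members (camera adjusted p = 0.000815; adjusted p = 0.256 with an estimated correlation), with the proteases Mcpt4 at -4.66 ± 0.59, Cma1 at -3.66 ± 0.43, Tpsb2 at -2.99 ± 0.58 and Cpa3 at -2.21 ± 0.43. The T cell list was lower as a whole (3.32e-06; adjusted p = 0.296 with an estimated correlation), although of its 12 members only Cd2 (-1.13 ± 0.12) passed both limits of a call. The same held for the NK cell list (0.00104; adjusted p = 0.256 with an estimated correlation), where 1 of 8 members was called, Nkg7 (-1.24 ± 0.14). The lists of B cells (0.00422), regulatory T cells (0.0349), MHC class I (0.00201) and MHC class II (0.0432) were lower with 0 members called. The adipocyte list was higher (0.0340), with 1 of 8 members called, Pparg (1.97 ± 0.52). None of these 5 held with an estimated correlation (adjusted p of 0.470 to 0.640). Of 9 plasma cell genes 2 were higher (0.0169; adjusted p = 0.393 with an estimated correlation), Igha and the joining chain Jchain (2.44 ± 0.35), while Sdc1 was at -0.08 ± 0.19 and Ighm at -0.10 ± 0.14. The matrix genes Fbln1 (3.09 ± 0.49), Lum (3.06 ± 0.41) and Dcn (1.58 ± 0.16) were the 3 of 8 fibroblast genes called higher (0.0132; adjusted p = 0.432 with an estimated correlation), while Col1a1 was at -0.02 ± 0.26. Of 16 cytokines 4 were lower, among them Tnf and Lta (-1.40 ± 0.20), and Il33 was higher at 1.81 ± 0.18 (0.0169; adjusted p = 0.476 with an estimated correlation). Il1rn (0.37 ± 0.46), Il7 (0.02 ± 0.33) and Csf1 (0.39 ± 0.16) also lay above 0 and did not pass the test. Nkx2-3, a transcription factor of gut and splenic vessels, had no read in the inguinal node and was at least 97.9-fold higher in the mesenteric node, against a limit of 3 counts over the 4 libraries. None of these counts moved when adjusted over the list alone. The 234 lower genes became 370 without mesenteric replicate 1 and 528 in a fit on all 60 libraries, and scaling by library totals gave 562 higher and 348 lower.

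The fourth comparison followed the intestine from small intestine to colon. Defa24 reached 33224 ± 7339 against 3.43 ± 1.64 CPM (log2 fold change 13.16 ± 0.28), AY761184, another alpha-defensin, was at least 7738-fold higher than in colon, where it had no read, and Defa30, Defa21, Defa22 and Defa17 had 3 counts or fewer in colon, with Defa30 at 11190 ± 2559 CPM. Reads of these copies may be shared. Lct, the lactase of the brush border (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318), was at least 1649-fold higher and the pentraxin Mptx2 at least 537-fold. The colon was higher in the amino acid transporter Slc6a14 (218 ± 12.4 CPM, at least 647-fold), the carbonic anhydrase Car1 (4241 ± 2296 against 2.20 ± 1.52 CPM, -10.83 ± 0.55), the proton pump Atp12a (at least 188-fold), the transglutaminase Tgm3 (1488-fold, 508 to 7220), and the cytochrome Cyp2d34 (1785-fold, 320 to 70600). It was also higher in the posterior Hox gene Hoxb13 (1034-fold, 286 to 8555), the hormone Insl5 (1285-fold, 230 to 50860) and Hoxa11os, which is antisense to Hoxa11 and may share its reads (at least 283-fold). Bounds take 3 counts over the 4 libraries for a tissue without reads, and ranges are 95% counting intervals. Both pool the counts of the 4 libraries of a tissue, so they cover counting error only and not the spread between libraries. No molecular identifiers are described. Colon replicate 2 stood at 430 CPM for Hoxb13 and 242 CPM for Insl5, against at most 193 and 121 CPM in the other colon libraries, and small intestine replicate 2 at 606 CPM for Mptx2, against at most 367.

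Of 10773 tested genes, 1457 were higher and 1309 lower in small intestine, or 921 and 2324 by library totals alone. All 11 enterocyte genes (camera adjusted p = 6.66e-10), all 8 Paneth cell genes (6.03e-08) and 9 of 11 lipid absorption genes (1.16e-07) were higher, each with adjusted p = 0.107 with an estimated correlation. The apolipoprotein Apoa4 differed 3884-fold (1075 to 32080) and the fatty acid binding protein Fabp1 by 10.82 ± 0.41 on the log2 scale, and the receptor Scarb1 went against the list at -0.70 ± 0.27. All 11 colonocyte genes were lower (9.33e-09; adjusted p = 0.107 with an estimated correlation), and 7 of 8 smooth muscle genes (1.77e-05; adjusted p = 0.256 with an estimated correlation), with Cnn1 at -2.65 ± 0.13. Of 8 goblet cell genes 5 were lower (0.0125; adjusted p = 0.343 with an estimated correlation), such as Retnlb (-8.21 ± 0.43) and Muc2 (-3.53 ± 0.14), while Tff3 gave 0.68 ± 0.13, Fcgbp 0.01 ± 0.17 and Zg16 0.02 ± 0.16. MHC class II genes were higher in small intestine in 4 of 7 cases (0.00572; adjusted p = 0.374 with an estimated correlation), with Ciita at 2.03 ± 0.27. The same held for 4 of 4 measured T cell genes (0.0323; adjusted p = 0.245 with an estimated correlation), with Trac at 2.67 ± 0.44. Each count was the same adjusted over the list alone. The mitochondrial rRNA share was 8.58% ± 1.11 of counts in small intestine and 0.810% ± 0.0846 in colon, and Malat1 0.152% ± 0.0191 against 0.0178% ± 0.00301.

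The fifth comparison set thymus, where T cells mature, against bone marrow. Tbata (517 ± 137 CPM, at least 1473-fold), the keratin Krt17 (161 ± 37.7 CPM, at least 423-fold), the transcription factors Pax1 (at least 238-fold) and Trp63 (at least 94.0-fold), Tdrd5 (at least 214-fold) and Slc46a2 (at least 163-fold) had no read in bone marrow, and Psmb11 (125 ± 10.9 CPM) differed 1016-fold (182 to 40170). Krt17 stood at 217 CPM in thymus replicate 4 and 135 to 146 CPM in replicates 1 to 3. Glycam1 was at 34.6 ± 37.2 CPM in thymus, with an SD above its mean, and at least 91.4-fold higher. Higher in bone marrow, Car1 (at least 991-fold), the ammonium transporter Rhag (at least 832-fold) and the adducin Add2 (at least 553-fold) had no read in thymus. Slc4a1 (ENSMUSG00000006574, chromosome 11, 102348824 to 102366203) was at 2231 ± 25.4 CPM and differed 13160-fold (3642 to 108700), and Ear6 differed 5870-fold (1053 to 231900).

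Of 12183 tested genes, 1860 were higher in thymus and 1980 lower, or 3696 and 1259 by library totals alone. The thymocyte (11 of 11) and thymic epithelium (8 of 8) lists were higher in thymus (camera adjusted p = 9.33e-09 and 6.01e-06; adjusted p = 0.0666 for each with an estimated correlation), as were 11 of 12 T cell genes (6.70e-08; adjusted p = 0.113 with an estimated correlation). Trbc2 differed by 6.05 ± 0.12 and Cd8a by 6.56 ± 0.16 on the log2 scale, and the cytokine receptor Il7r went against the list at -0.92 ± 0.14. Lower in thymus were 9 of 9 neutrophil precursor genes (1.93e-08; adjusted p = 0.0666 with an estimated correlation), 10 of 10 erythroid genes (6.85e-10; adjusted p = 0.0666 with an estimated correlation), 11 of 11 B cell genes (7.48e-06; adjusted p = 0.314 with an estimated correlation) and 6 of 13 cell cycle genes (0.000164; adjusted p = 0.0837 with an estimated correlation). Ngp gave -10.65 ± 0.17, Pax5 of the B lineage -4.25 ± 0.17 and Mki67 -1.76 ± 0.09. Of 16 chemokines 9 were higher in thymus (0.0264; adjusted p = 0.295 with an estimated correlation), among them Ccl25 (5.22 ± 0.13), and Ccl6 (-4.78 ± 0.12), Ccl9 (-3.28 ± 0.15) and Cxcl14 (-1.73 ± 0.34) were lower, and Cxcl12 was at -0.48 ± 0.13. Of 13 pattern recognition receptors 9 were lower (0.00552; adjusted p = 0.256 with an estimated correlation), Tlr12 was higher at 2.14 ± 0.26 and Ddx58 gave 0.10 ± 0.12. Adjusted over the list alone, every count was the same.

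The sixth comparison set blood against spleen, its filter. Nrgn, neurogranin (ENSMUSG00000053310, chromosome 9, 37544492 to 37552904), was at 5104 ± 736 CPM in blood against 58.96 ± 10.7 CPM in spleen (log2 fold change 6.43 ± 0.14), where replicate 4 held 42.97 CPM and the others at least 63.3 CPM. The protease inhibitor Ctla2a was at 4088 ± 682 against 69.8 ± 8.39 CPM (5.87 ± 0.13). Also higher in blood were Gchfr (6.25 ± 0.20), the chemokine Cxcl2 (6.30 ± 0.75), the small cytoplasmic RNAs Rny1 (5.84 ± 0.40) and Rny3 (5.89 ± 0.43), the pseudogene Hspd1-ps4 (80.2-fold, 26.9 to 393), whose reads its parent gene may share, and the lipoxygenase Alox15 (6.53 ± 1.10). Alox15 was 337 CPM in blood replicate 3 and 10.8 to 54.98 CPM in the others. Spleen was higher in Coch (721 ± 41.9 against 0.475 ± 0.360 CPM, -10.20 ± 0.18), Npnt (1002-fold, 180 to 39620) and genes without a read in blood, namely Hs6st2 (at least 188-fold), Tcf21, a mesenchymal transcription factor (at least 126-fold), Hmcn1 (at least 119-fold), Ramp2 (at least 108-fold), AU021092 (at least 79.8-fold) and Adamtsl2 (at least 78.7-fold). The globin Hba-a1 was at 1414 ± 305 CPM in blood, 1489 ± 284 in spleen and 49241 ± 8113 in bone marrow, values looked up after the fits.

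Of 12157 tested genes, 972 were higher in blood and 1695 lower. All 7 platelet genes were higher (camera adjusted p = 4.06e-07; adjusted p = 0.177 with an estimated correlation), with the integrin Itga2b at 5.67 ± 0.16 and the chemokine Pf4 at 5.02 ± 0.13. Higher too were 7 of 8 mature neutrophil genes (1.57e-05; adjusted p = 0.296 with an estimated correlation), with Csf3r at 3.75 ± 0.21 and S100a9 at 3.27 ± 0.17. Of 11 immediate early and heat shock genes 8 were higher (0.000991; adjusted p = 0.228 with an estimated correlation), among them Fos (4.28 ± 0.13) and Fosb (4.37 ± 0.26), while the heat shock genes Hspa1b (-4.14 ± 0.51) and Hspa1a (-3.37 ± 0.56) were lower. Lower in blood were 7 of 7 spleen stroma genes (5.06e-06; adjusted p = 0.0666 with an estimated correlation), 7 of 7 fibroblast and matrix genes (4.82e-05; adjusted p = 0.256 with an estimated correlation), with Col1a2 at -7.06 ± 0.21, 8 of 10 complement genes (0.000523; adjusted p = 0.264 with an estimated correlation) and 10 of 13 cell cycle genes (0.00131; adjusted p = 0.417 with an estimated correlation), with Mki67 at -2.41 ± 0.16. Of 9 plasma cell genes 4 were lower (0.00489; adjusted p = 0.343 with an estimated correlation), with Jchain at -7.30 ± 0.28, while Sdc1 was at 0.14 ± 0.29. The B cell list gave a camera adjusted p of 0.0333 (adjusted p = 0.296 with an estimated correlation), with 1 of 11 members higher, Fcer2a (1.54 ± 0.11), and 1 lower, Cr2 (-1.99 ± 0.08), while Ms4a1 gave -0.32 ± 0.11. Each of these counts was unchanged when adjusted over the list alone. Over the 4 pairs, 58 of 136 lists were called with the preset correlation and 0 with an estimated one.

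**Figure D4:**
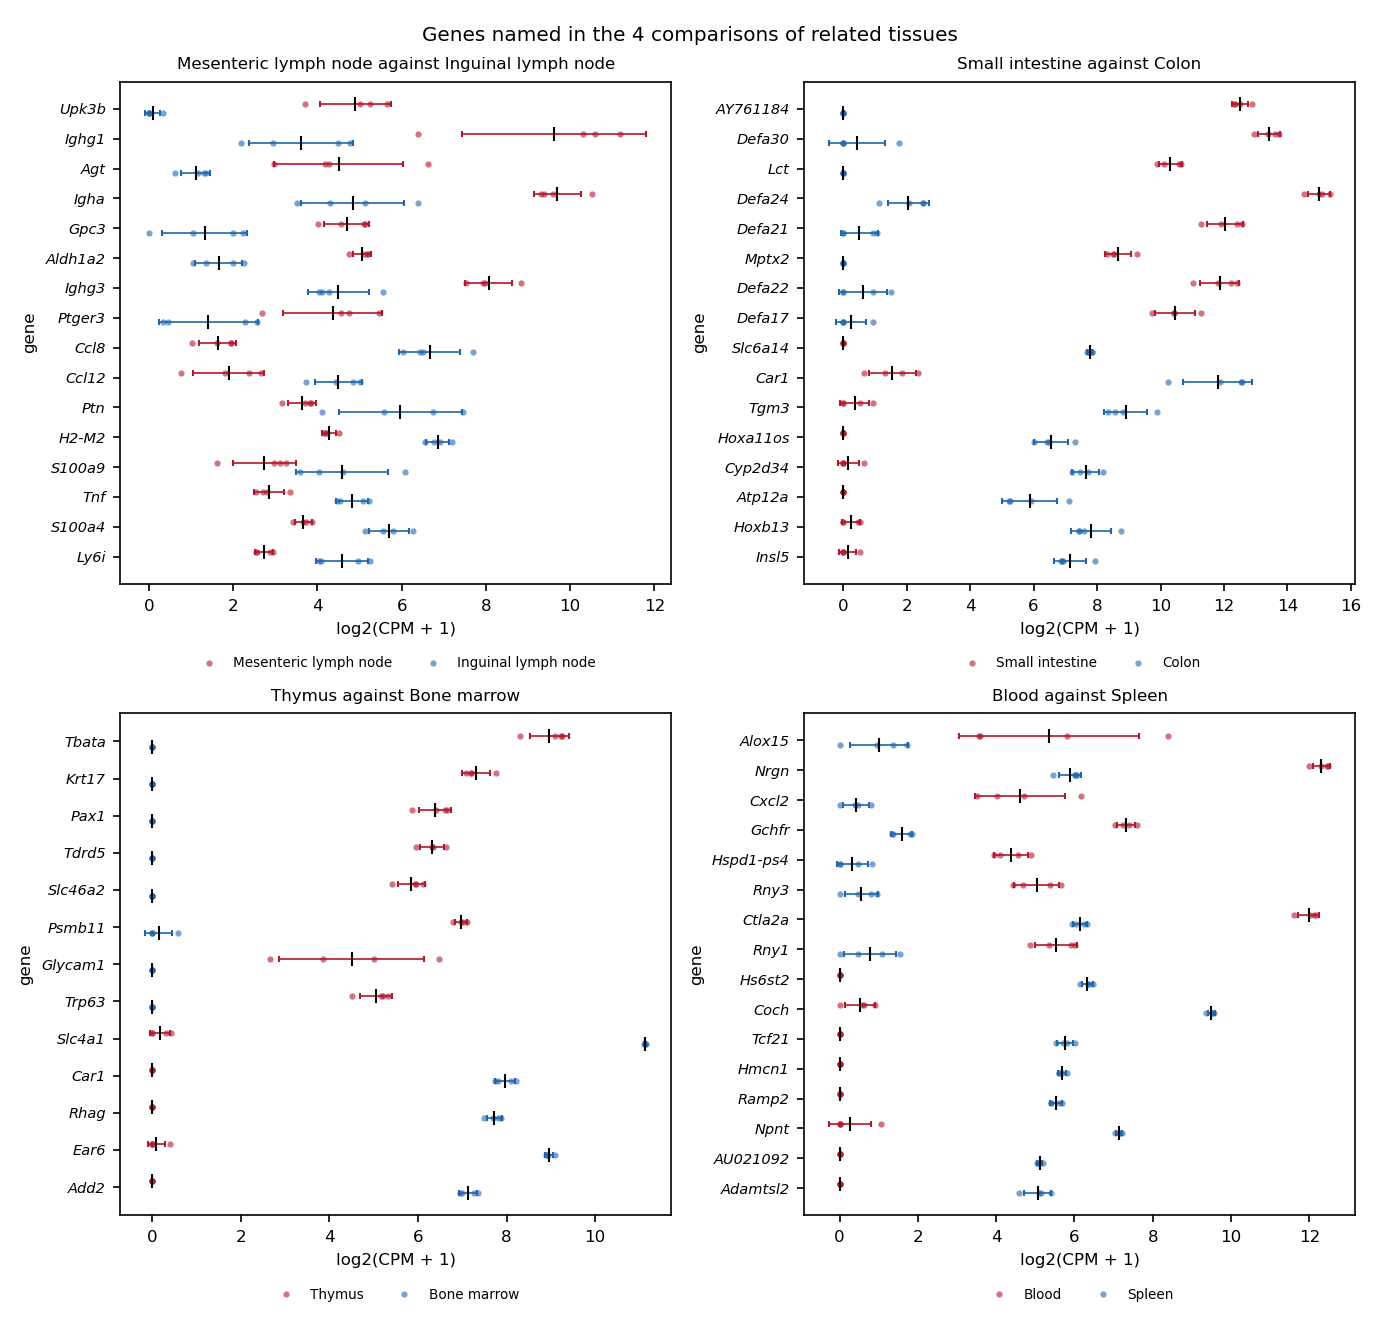
Log2(CPM + 1) of genes named by the rule, as far as reported here, in single libraries (points) with mean ± SD (bars) for the 4 pairs of tissues, 4 libraries per tissue, 1 panel per pair with genes on the vertical axis. In the panel of the lymph nodes Igha averages 883 CPM in the mesenteric and 36.4 CPM in the inguinal node.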

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

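The tests of depth, of mitochondrial transcripts and of separate capture in colon and in lung, and the test of carry-over in the pancreatic pattern, were chosen only after the result was seen.

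Of 295 groups of 4 libraries examined, 22 (7.46%) held 1 library far from the other 3 by the ratio of its gap to the range of the group. For independent groups of normally distributed values chance gives about 1 in 20. The groups examined share libraries and include levels picked for this text, such as Defa24 in brain and liver. The 7.46% can therefore not be set against that share. The numbers of genes detected at equal depth were 14904 in blood replicate 1, against 13089 to 13173 in the other blood libraries, and 11487 in liver replicate 2, against 11600 to 11610. Spleen replicate 2 held 0.8996% Malat1 (others 0.980% to 0.995%) and spleen replicate 1 held 0.03437% Neat1 (others 0.02998% to 0.0306%).

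Colon replicate 2 lay apart from the other colon libraries in 5 genes. It held more Mptx1 (3440 CPM, others 992 to 1132), Sval1 (739.5 CPM, others 364 to 390), Hoxb13 (430.3 CPM, others 171 to 193) and Insl5 (241.5 CPM, others 116 to 121), and less Muc2 (9169 CPM, others 12820 to 13080). In the female reproductive tract, Sprr2f was 2982 CPM in replicate 4 and 8.38 to 51.9 CPM in the others. In mesenteric lymph node, Madcam1 was 60.7 CPM in replicate 3 (others 53.8 to 54.9), Agt 97.3 CPM in replicate 4 (others 6.83 to 18.3) and Igha 1464 CPM in replicate 2 (others 628 to 769). Ighg3 was 46.37 CPM in inguinal lymph node replicate 2 (others 15.4 to 18.4). Single libraries also stood apart for Mptx2 in small intestine replicate 2 (606 CPM, others 317 to 367), Krt17 in thymus replicate 4 (216.7 CPM, others 135 to 146), Alox15 in blood replicate 3 (337.4 CPM, others 10.8 to 54.98), Il1b in blood replicate 3 (112.3 CPM, others 172 to 182), Nrgn in spleen replicate 4 (42.97 CPM, others 63.3 to 66.2), C3 in liver replicate 4 (8417 CPM, others 7330 to 7505) and Defa24 in brain replicate 3 (393.8 CPM, others 4.61 to 8.53) and liver replicate 4 (241.5 CPM, others 12.8 to 27.3). Apart from Defa24, no explanation of these values was tested.

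The 8 colon and lung libraries held less mitochondrial rRNA (0.233% to 0.928% of counts, against 4.33% to 40.6% in the other 52), Malat1 (0.0151% to 0.0282%, against 0.131% to 1.65%) and annotated rRNA (0.0107% to 0.0136%, against 0.288% to 5.87%), but more reads of nuclear protein-coding genes (93.4% to 96.7%, against 42.4% to 88.5%) and more Neat1 (0.0953% to 0.206%, against a median of 0.0352% and at most 0.142%). A preparation that captured less RNA without a poly(A) tail should lower histone transcripts and miscellaneous RNA as well, and 8 and 39 of the 52 other libraries exceeded the highest colon library in these classes, and 29 and 35 the highest lung library. The bound first set for excluding it, a high level in either class, was met by the histones of colon and was changed to both classes after the result was seen, because the histone share of the other libraries itself ran from 0.0109% to 0.147% and a high level could hide a loss, so this explanation stays open. Few mitochondrial transcripts of any kind is argued against by the mitochondrial protein-coding transcripts, in which 11 other libraries lay below the lowest of colon and lung, and lower depth by 3 other libraries no deeper, whose lowest mitochondrial rRNA share was 8.93 times the highest of colon and lung. Other differences in preparation may be the source too: the titles number the 4 libraries of each tissue consecutively, with 17 to 24 for colon and lung, but a batch of colon and lung cannot be told apart from the tissues, and a biological difference of these tissues stays open and was not tested.

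Brain replicate 3 and liver replicate 4 held transcripts of small intestine. A likely explanation is that RNA or reads of small intestine entered these libraries, since genes restricted to small intestine were mostly raised in a shared ratio to their level there. Of those with at least 5 expected counts, 74 of 79 in brain replicate 3 (93.7%) and 34 of 42 in liver replicate 4 (80.95%) lay within 3 times the median ratio, which was 0.873% and 0.431%. Reads shared between defensin copies are argued against by 43 restricted genes other than defensins in the liver library, and 82 in the brain library, with more counts than in the other 3 libraries of the tissue together. Whether the transfer took place at dissection, in library preparation or in sequencing stays open.

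Spleen replicate 4 and colon replicate 2 held transcripts of the exocrine pancreas, with summed levels of 9962 and 7261 CPM against at most 297.5 and 213.6 CPM in the other libraries of these tissues. All 11 members of the exocrine pancreas list were above the other 3 libraries in both, and of abundant ones Cela1 stood at 1273 and 1301 CPM and Prss2 at 1101 and 709.6 CPM, so pancreas taken along at dissection is a candidate source. Carry-over from any of the other 58 libraries is argued against, since the highest of them, female reproductive tract replicate 3, held 1684 CPM, 0.232 of the lower of both levels. Carry-over between spleen replicate 4 and colon replicate 2 was not tested. The numbers in the titles pass from 44 (liver) to 49 (small intestine), and those between belong to none of the 60 libraries. Carry-over from a library outside the 60 was not tested and stays open.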

How the results depend on the processing

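The fit of nuclear protein-coding genes, the fit without 6 libraries in doubt (female reproductive tract 3 and 4, brain 3, liver 4, spleen 4, colon 2) and the fit without colon and lung were chosen only after the result was seen.

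The genes named by the rule kept their direction and their call in every setting in which they were fitted: 129 of 129 with DESeq2 size factors, with library totals, without a filter, with the replicate block and with DESeq2, 121 of 121 with protein-coding genes, 97 of 97 without 6 libraries, 59 of 59 without colon and lung, 64 of 64 in a fit of all 60 libraries, and 772 of 772 with 1 replicate left out. The named genes were chosen from the same data for large differences, so the choice itself favoured their stability. Counts of called genes stayed within 1.5 times the reported count in 40 of 40 cases with DESeq2 size factors, 28 of 28 without colon and lung, and 250 of 252 with 1 replicate left out. With library totals 23 of 40 counts did so, and without a filter 27 of 40. The nearest library was of the same tissue for 60 of 60 libraries with Pearson correlation too.

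With the replicate number as a block, 40 of 40 counts stayed within 1.5 times the reported count, such as 771 higher and 237 lower for mesenteric against inguinal lymph node. The labels do not say that a number marks a mouse, so the numbers were not used as pairs. Over 420 pairs of libraries from different tissues with the same number, the mean correlation of deviations from the tissue means was 0.0146 (-0.139 to 0.210), against -0.00476 for different numbers. Of these pairs, 7 exceeded 0.1, and 3 of them were mesenteric with inguinal lymph node (0.210, 0.107 and 0.197, with -0.0130 for number 2). On average, 48 of 60 libraries correlated best with their own number, a hint from the data and not from the design that libraries with the same number may share a mouse or another factor. Replicates of a tissue were separate measurements, with a chi-square per degree of freedom of 1.60 to 22.1 over 90 pairs and 0 identical columns.

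Scaling by library totals moved the median log2 fold change of all genes by -1.26 (heart) to 0.60 (thymus against bone marrow), and DESeq2 size factors by -0.10 to 0.12. With totals, lower genes numbered 411 in female reproductive tract, 2920 in kidney, 1462 in lung, 510 in mesenteric lymph node and 981 in spleen. Higher and lower genes numbered 1499 and 8430 in heart, 4835 and 716 in inguinal lymph node, 1811 and 7497 in liver, 5525 and 1353 in thymus, 921 and 2324 for small intestine against colon, and 3696 and 1259 for thymus against bone marrow. Heart had 90 restricted genes. These shifts follow from the construction of the scaling.

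Without a filter on low counts more genes were tested. Higher genes numbered 5400 in blood, 9090 in brain, 6768 in female reproductive tract, 4836 in inguinal lymph node, 4800 in mesenteric lymph node, 5024 in spleen, 5506 in thymus, 2622 for small intestine against colon and 3240 for thymus against bone marrow. Higher and lower genes numbered 1090 and 509 for the lymph nodes, and 1516 and 2830 for blood against spleen. With protein-coding genes fewer were tested, and higher genes numbered 2115 in inguinal lymph node, 2180 in spleen and 2284 in thymus, and lower genes 1492 in lung.

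DESeq2 called more lower genes: 2926 in inguinal lymph node, 2868 in kidney, 1713 in mesenteric lymph node, 2909 in spleen and 5608 in immune tissues. The cause was not tested. It shared 875 of the 950 genes called by edgeR between the lymph nodes, 2706 of 2766 between small intestine and colon, 3800 of 3840 between thymus and bone marrow, and 2608 of 2667 between blood and spleen. In a fit of all 60 libraries, lower genes numbered 528 for the lymph nodes and 2763 for blood against spleen, and higher genes 2903 for small intestine against colon and 3281 for thymus against bone marrow, and the cause was not tested.

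With 1 library left out, lower genes for the lymph nodes ranged from 213 to 370, the highest without mesenteric replicate 1. With 1 replicate number left out in every tissue, restricted genes of mesenteric lymph node ranged from 2 to 6, the highest without replicate 2. Without 6 libraries, female reproductive tract had 88 restricted genes. Its replicate 3 had 353605 counts and 5.87% annotated rRNA (replicates 1 and 2, 1.02% and 1.14%), and replicate 4 had 60.04 times as much mitochondrial rRNA as mitochondrial protein-coding RNA (4.90 and 6.18 times). The cause of these changes was not tested. Thymus replicate 4, not among the 6, had a ratio of 28.34 (others 5.72 to 7.02) and 0.488% mitochondrial protein-coding RNA (others 1.57% to 1.91%). Its chi-square per degree of freedom with the other thymus libraries was 6.00 to 6.83, against 1.98 to 2.85 among these. With any 1 replicate left out, counts for thymus stayed within 1.5 times the reported count.

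At 2 times the next tissue, a wider limit by construction, restricted genes numbered 145 in blood, 330 in bone marrow, 152 in colon, 109 in female reproductive tract, 625 in heart, 16 in inguinal lymph node, 351 in kidney, 747 in liver, 312 in lung, 8 in mesenteric lymph node, 298 in small intestine, 24 in spleen and 231 in thymus. With an estimated correlation, camera called 105 of the 320 lists of single tissues, 16 of the 39 of immune tissues and 0 of the 58 of pairs, of which 25 of the 136 tested had an unadjusted p under 0.05.

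Depth limits the detection of weak genes. Without thinning, the mean number of detected genes was 17962 in blood, 18244 in bone marrow, 21937 in brain, 15608 in colon, 19527 in female reproductive tract, 18008 in heart, 20858 in inguinal lymph node, 19774 in kidney, 16764 in liver, 15750 in lung, 20424 in mesenteric lymph node, 19320 in skin, 18974 in small intestine, 19962 in spleen and 20324 in thymus.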

Other observations

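The lists and genes in the next 3 paragraphs were chosen after their values were seen, while the splits of the samples were planned. Fitted log2 fold changes are against the mean of the other 14 tissues, some of which hold no reads of these genes, and are then no bound.

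Some genes of one organ were also raised in another. In kidney, 4 of 6 genes of ileal bile acid transport were higher (camera adjusted p = 0.0241, and 0.266 with an estimated correlation). The transporter Slc10a2 stood at 153 ± 20.9 CPM (SD, n = 4), with a log2 fold change of 8.81 ± 0.31 (SE), followed by Slc51b at 7.0 ± 0.25, the receptor Nr1h4 at 5.79 ± 0.20 and Slc51a at 4.09 ± 0.27. Fabp6 and Fgf15, which were not called, were close to absent there. In lung, 8 of 10 cardiomyocyte genes were higher (adjusted p = 0.00539, and 0.218 with an estimated correlation), led by Myl7 (97.9 ± 10.2 CPM, log2 fold change 6.54 ± 0.41) and Actc1 (169.9 ± 32.8 CPM, log2 fold change 5.31 ± 0.19). In blood against spleen, 3 of 6 cardiomyocyte genes were higher (adjusted p = 0.0162, and 0.507 with an estimated correlation). Actc1 was 122-fold higher (95% interval 21.2 to 4874), Myl2 69.5-fold (18.7 to 583) and Myh6 at least 38.02-fold. Genes abundant in some other organs were also higher in blood, and the leading gene of lung was lower. Of 4 hepatocyte genes 3 were higher (median log2 fold change 4.91), although that list was not called (adjusted p = 0.0610, and 0.517 with an estimated correlation). Apoa1, of liver and small intestine, was 84.4-fold higher (22.8 to 706), Kap, of kidney, 103-fold (17.9 to 4134), and Nlrp6, of small intestine and liver, 145-fold (25.4 to 5800). Scgb1a1, of lung, had no read in blood and was at least 33.7-fold higher in spleen, and of 4 lung epithelium genes 0 were higher and 1 lower in blood (adjusted p = 0.735, and 0.792 with an estimated correlation).

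Further lists of cell types were higher in tissues where other lists led. Spleen had 5 of 6 eosinophil genes higher (adjusted p = 0.0385, and 0.189 with an estimated correlation), with the receptors Ccr3 (28.1 ± 5.04 CPM, log2 fold change 5.08 ± 0.24) and Il5ra (3.80 ± 0.30), while Siglecf gave -0.97 ± 4.18 and did not pass the test. Inguinal lymph node had 4 of 5 mast cell genes higher (adjusted p = 0.00883, and 0.0806 with an estimated correlation), led by Mcpt4 at 12.2 ± 4.50 CPM and 4.71 ± 0.29. Colon had 6 of 7 genes of peripheral nerve and enteric neurons higher, which held with an estimated correlation (adjusted p = 0.00348 and 0.0349), such as Elavl4 (4.08 ± 0.42), with Uchl1 most abundant at 43.2 ± 5.03 CPM. All 8 adipocyte genes were higher in mesenteric lymph node (adjusted p = 1.57e-05, and 0.179 with an estimated correlation), such as Cfd (5.58 ± 0.34) and Adipoq (5.35 ± 0.31).

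In skin, 9 of 11 immediate early and heat shock genes were higher (adjusted p = 0.000133, and 0.141 with an estimated correlation), with Hspa1b at 3.99 ± 0.21 and Fosb at 3.81 ± 0.24. The numbers of members called in these lists were the same when adjusted over the list alone.

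In every comparison only 1 split, the real one, gave as many called genes, which is the smallest share that these numbers of splits allow. Of 21 splits per tissue, the real one and the highest other called 6663 and 2606 genes for blood, 6267 and 3306 for bone marrow, 8125 and 1807 for brain, 5945 and 2748 for colon, 5270 and 1618 for female reproductive tract, 6232 and 4562 for heart, 4417 and 2174 for inguinal lymph node, 5810 and 1864 for kidney, 6524 and 2878 for liver, 5402 and 1643 for lung, 4037 and 1996 for mesenteric lymph node, 4607 and 2032 for skin, 5271 and 1947 for small intestine, 5003 and 1548 for spleen, and 5761 and 1699 for thymus. For immune tissues the real split called 7133 genes. The highest other called 636 when libraries were relabelled (21 splits) and 5420 when whole tissues were reassigned (100 splits), in a split that kept the 6 immune tissues together. For the pairs, with 35 splits each, the real split called 950 genes for the lymph nodes, 2766 for small intestine and colon, 3840 for thymus and bone marrow, and 2667 for blood and spleen, and the highest other called 0 in each. Every other split of a pair mixes both tissues, and relabelled libraries mix tissues as well, which widens the spread within groups. The counts of these other splits therefore give no rate of false calls.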
